A study of Homo sapiens with 6 samples.

How the data were processed

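Total RNA from PLC/PRF/5 cells transfected with a control siRNA (3 samples) or with siRNAs against SLU7 (3 samples) was hybridised to Affymetrix Human Exon 1.0 ST arrays, 1 sample per array with a single biotin label. Per the labels, the authors used the core chip definition of the aroma.affymetrix project, which gives 1 value per transcript cluster, and the submitters' processing notes name RMA, a method that corrects background, normalizes and summarises probes. Whether RMA was run on all arrays together, the genome build and the annotation release are not given in the sources used here. The deposited values are on the log2 scale, as read from their range (about 0.96 to 14.5), and the analysis started from them: no probe intensities, detection calls or scan dates were used here. Summarising all core probe sets of a gene into 1 value means that exon skipping or intron retention cannot be read from these values, and that a change in exon use can appear as a change in level. The series design text names a single control siRNA while the sample descriptions number it from 1 to 3, and those numbers were read as replicate numbers.

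Gene names came from GEO's platform annotation. Of 18708 clusters, 16287 had 1 gene symbol, 674 had several and 1747 had none in that table. Symbols were brought up to date where an older symbol belonged to exactly 1 gene of the RefSeq table of assembly GRCh38.p14 (2179 changed, and 16202 of the 16287 were then found in that table), which served for names only. No coordinates are given because the build of the array annotation is not named. Only clusters with 1 symbol were named. In gene lists each gene was represented by its brightest cluster over all 6 arrays, which gave 15949 genes, and 744 of the 829 listed genes were measured.

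Groups were compared with limma (version 3.58.1, R 4.3.3) using lmFit and eBayes without a trend on the deposited log2 values, with group as the only term, no filter on dim clusters, and Benjamini-Hochberg adjustment over all clusters at a threshold of 0.05. Fold changes are 2 to the power of the log2 difference between group means. The prior had 4.49 degrees of freedom beside 4 residual ones. Lists of genes were tested with camera (preset correlation 0.01, adjusted over 27 lists) and, as alternatives, with the correlation estimated from the residuals and with fry, which asks whether a list's genes move one way without comparing them with other genes. Each list's median was also placed among 10000 random lists matched on mean expression in 20 bins. The lists were the following: hepatocyte transcription factors, secreted proteins, oncofetal markers, gluconeogenesis and amino acid catabolism, glycolysis, hypoxia, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, drug metabolism, replication, mitosis, cohesion, p53 targets, stress and unfolded protein response, interferon, inflammation, acute phase, second-step splicing with SLU7 partners, small nuclear ribonucleoproteins, SR proteins and hnRNPs, ribosomal proteins, oxidative phosphorylation, mesenchymal and epithelial genes, and markers of blood and endothelial cells and of fibroblasts and stellate cells.

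The design, the lists, the alternative settings and the rule for naming genes were fixed before the data were examined. The rule names SLU7, the 8 largest rises and the 8 largest falls among called clusters with 1 gene symbol and no overlap between groups, and from each list up to 3 called members (2 where camera did not call the list). It gave 29 genes. Members named because 5 or fewer passed over a list alone were chosen after their values were seen. The alternative settings were a block for replicate number, a filter on the dimmer clusters, quantile normalization, median centring, an intensity trend with robust shrinkage, array weights, a threshold of 0.01, the mean of all clusters of a gene, and leaving out each array. A block for the 2 arrays that stand apart, and an analysis of the other 4, were added after seeing the data.

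No 2 arrays were copies of each other: pairs shared the exact value in at most 9 clusters and correlated at 0.926 to 0.974. On data simulated with these means and spreads for the comparison of SLU7 siRNA with control siRNA (18708 clusters, 20 simulations, 200 changed clusters each), the limma test recovered 84.2% of changes of 2 log2 units and 6.2% of changes of 1, with 6.9 false calls on average. In these simulations, where clusters varied independently, changes of 2-fold in single genes were therefore mostly out of reach of 3 arrays per group. Real clusters vary together between arrays and the number truly changed is not known, so the shares recovered may differ there.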

Results

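Gene expression was measured in PLC/PRF/5, an established human hepatocellular carcinoma cell line, 48 h after transfection with small interfering RNA (siRNA). SLU7, the targeted gene, encodes a splicing factor that acts in the second catalytic step of pre-mRNA splicing. The design addresses what changes in the transcriptome of these liver tumour cells when SLU7 is reduced, in a study whose title concerns liver differentiation, metabolism and quiescence. A control group of 3 arrays (an siRNA against an irrelevant target) was compared with a knockdown group of 3 arrays (siRNAs against SLU7), all on the Affymetrix Human Exon 1.0 ST array. Each array gave 1 log2 expression value for each of 18708 transcript clusters, which are groups of probe sets that together cover a gene. The array medians lay between 6.61 and 6.63 log2 units. The number of arrays limits the precision, and the typical standard error of a log2 difference between the groups was 0.312. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

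SLU7 itself (transcript cluster 2884684) was lower in every knockdown array than in every control array. Its mean was 7.38 ± 0.46 (SD, n = 3) log2 units with control siRNA and 5.87 ± 0.31 (SD, n = 3) with SLU7 siRNA. The difference of -1.51 ± 0.31 (SE) log2 units corresponds to a 2.84-fold lower level (95% interval 1.73 to 4.68), or 35.2% of the control level. Over all transcript clusters the limma adjusted p of SLU7 was 0.078, outside the 0.05 threshold. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow. Control replicate 2 and SLU7 replicate 1 stood apart from the other 4 arrays on the first principal component, across the groups. The SLU7 difference was -1.67 within the other 4 arrays, and SLU7 was 1.17 log2 units higher in control replicate 2 than in SLU7 replicate 1.

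**Figure D1:**
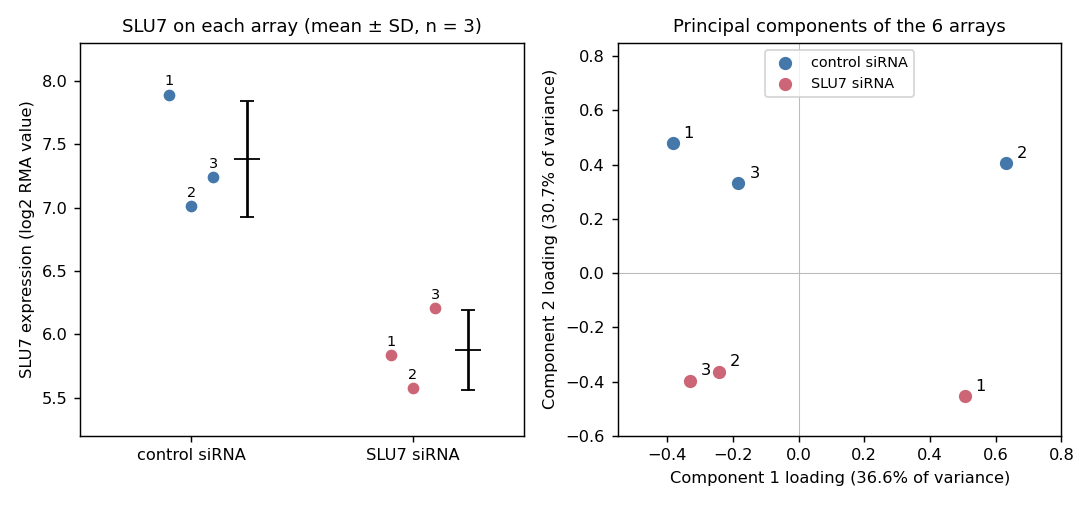
Left, SLU7 expression (log2 value) on each of the 3 control and 3 SLU7 siRNA arrays, numbered by replicate, with mean ± SD; the control arrays lie between 7.01 and 7.89 and the knockdown arrays between 5.58 and 6.21. Right, loadings of the 6 arrays on the first component (36.6% of the variance) and the second (30.7%); the second separates the groups, and the first sets control replicate 2 and SLU7 replicate 1 apart from the other 4 arrays.

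After SLU7 siRNA, 25 transcript clusters rose and 56 fell at an adjusted p under 0.05, which is 0.433% of those tested. Of these, 18 that rose and 53 that fell carried a single gene name. Every call was at least 2.72-fold. Among called clusters with a single gene name, the largest rises were in GCNA (germ cell nuclear acidic protein, named ACRC in the array annotation), by 3.21 ± 0.30 (SE) log2 units or 9.27-fold, and in CDKN2AIP, a protein that binds the tumour suppressor ARF, by 2.74 ± 0.44 log2 units or 6.69-fold. PITHD1 rose 4.87-fold, the zinc finger gene ZNF75A 4.53-fold, TMEM81 4.45-fold and THAP12 4.35-fold. THAP12 has 1 other cluster, which was not called. PRKAB1, a regulatory subunit of the energy sensor AMP-activated kinase, rose 4.0-fold and HAUS2, a subunit of the augmin complex of the mitotic spindle, 3.96-fold. The largest fall among called clusters with a single gene name was in PCK1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, by 2.89 ± 0.37 (SE) log2 units or 7.40-fold. It was followed by VIL1 (villin, an actin-bundling protein of microvilli) at 7.04-fold lower, the vesicle GTPase RAB26 at 6.95-fold, RASL11A at 6.92-fold and FXYD3, a regulator of the sodium pump, at 6.57-fold. FRAS1, a basement membrane protein, fell 6.33-fold, MRCL3, a myosin light chain gene, 6.28-fold and CKB, the brain-type creatine kinase, 6.23-fold. Some of these folds are uncertain because a group lay below the lower quartile of its arrays (4.86 to 4.98 log2 units): GCNA and TMEM81 with control siRNA (3.75 and 4.64) and MRCL3 in both groups (4.35 and 1.70). MRCL3 also has a near-identical paralog.

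**Figure D2:**
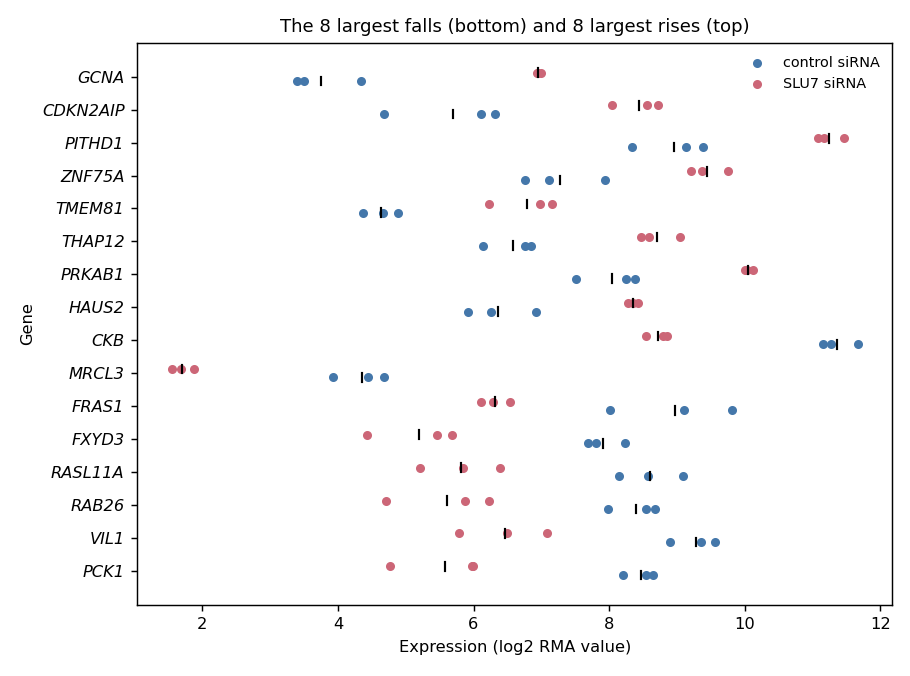
Expression (log2 value) on each array for the 8 called genes with the largest rises and the 8 called genes with the largest falls. Points are the 3 arrays of each group and vertical ticks their means. In each gene the groups do not overlap, and GCNA went from a mean of 3.75 to 6.96 while PCK1 went from 8.47 to 5.58.

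In all 81 calls the 3 arrays of each group lay apart without overlap. That held for 3527 clusters, 18.9% of the table, where chance alone gives 10%. Without any 1 of the 6 arrays, no cluster passed the limma threshold (1833 to 2573 clusters at an unadjusted p under 0.05 each time). Each of the 28 called genes named here kept its direction, which groups without overlap cannot lose when arrays are left out. Across these analyses the log2 difference of PFKP ran from -2.58 to -2.35 and that of GCNA from 3.04 to 3.51, and the widest ranges were those of FRAS1 (-3.14 to -2.25), CDKN2AIP (2.23 to 3.05) and RAB26 (-3.11 to -2.35). Without both arrays that stand apart on the first component, no cluster passed either (2922 at an unadjusted p under 0.05). With those 2 arrays kept and entered as a block, 357 clusters were higher and 426 lower, among them all 81, and SLU7 had an adjusted p of 0.043. That block was read off the first component of these same arrays, which lowers the residual error by selection. Its limma p-values are therefore likely too small and its calls too many.

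Genes of the hypoxia response and of glycolysis were lower as groups with camera's preset correlation, but neither list passed with an estimated one (adjusted p = 0.109 with an estimated correlation for both). The self-contained test fry called both lists lower (adjusted p = 0.00982 for hypoxia and 4.24e-04 for glycolysis). Of 26 measured hypoxia genes other than glycolytic enzymes, 25 had a negative difference, with a median of -0.83 log2 units or 1.77-fold lower. NDRG1, a hypoxia-induced differentiation gene, fell 4.85-fold and CA9, the carbonic anhydrase that is a standard target of hypoxia-inducible factor, fell 4.52-fold (from 10.46 ± 0.06 to 8.28 ± 0.30 log2 units, SD, n = 3). The other 24 did not pass the test over all genes, and 10 members fell when adjusted over the list alone. The median was -0.88 within the 2 arrays that stand apart and -0.86 within the other 4, the former being a difference between single arrays with no error, as in the lists that follow. The limma camera test, which compares a list with all other genes, gave an adjusted p of 2.32e-10 with its preset correlation between genes, and adjusted p = 0.109 with an estimated correlation. In glycolysis, 20 of 24 genes were below 0, with a median of -0.37. PFKP, the platelet-type phosphofructokinase, fell 5.45-fold (from 10.91 ± 0.19 to 8.46 ± 0.23) and PGK1, phosphoglycerate kinase, 3.10-fold, while 22 members did not pass. Adjusted over the list alone, 7 glycolytic genes fell, and the median was -0.51 within the pair of arrays and -0.40 within the other 4. The list had a camera adjusted p of 1.66e-06, and adjusted p = 0.109 with an estimated correlation.

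Genes of hepatocyte metabolism and secretion were lower as groups with the preset correlation, and not with an estimated one (adjusted p = 0.12 with an estimated correlation for both lists). Fry called both lower (adjusted p = 5.9e-04 for gluconeogenesis and amino acid catabolism, 0.0231 for secreted proteins). It also called the list of hepatocyte transcription factors (adjusted p = 0.0375). Among 29 genes of gluconeogenesis and amino acid catabolism, PCK1 and PCK2, the mitochondrial carboxykinase (3.34-fold), fell, and 27 did not pass. Their median was -0.31, with 23 below 0 (-0.35 within the pair and -0.34 within the other 4), and 6 fell when adjusted over the list alone. The camera adjusted p was 0.00132, and adjusted p = 0.12 with an estimated correlation. The 44 measured plasma proteins and apolipoproteins had a median of -0.43, or 1.35-fold lower, with 36 below 0 (-0.45 within the pair and -0.35 within the other 4). None passed over all genes and 5 fell when adjusted over the list alone. Those 5, named because they are few, were APOC3 (-1.73 log2 units), SERPINA5 (-1.60), F10 (-1.33), APOM (-1.19) and F2 (-1.14), of which SERPINA5 reached a dim 3.37 log2 units that leaves its size uncertain. This list had a camera adjusted p of 7.99e-06, and adjusted p = 0.12 with an estimated correlation. The 19 measured hepatocyte transcription factors had a median of -0.16 (-0.25 within the pair and -0.20 within the other 4) and a camera adjusted p of 0.0444 (adjusted p = 0.186 with an estimated correlation). None passed over all genes and 2 fell over the list alone, ESRRA (-1.18) and NR1I2 (-1.09), the pregnane X receptor, whose size is uncertain because both groups were dim (3.66 and 2.57 log2 units). The list's call was also lost without the dimmer clusters (adjusted p = 0.207), with quantile normalization (0.0521), with array weights (0.0607), with the array split as a block (0.0606) and in the 4 arrays alone (0.1). It was lost in 3 of the 6 analyses without 1 array (control replicate 1, adjusted p = 0.0717; control replicate 3, adjusted p = 0.108; SLU7 replicate 1, adjusted p = 0.141), where the median ran from -0.32 without control replicate 1 to -0.10 without control replicate 2.

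In drug metabolism and bile acid handling, CYP4F3, a cytochrome that hydroxylates fatty acids and leukotrienes, fell 6.0-fold, to a dim 4.65 log2 units that leaves the fold uncertain, and ABCC2, the canalicular export pump for conjugated bilirubin, fell 5.41-fold. The other 30 members did not pass, 2 fell when adjusted over the list alone, and the list of 32 genes had a median of -0.22 and a camera adjusted p of 0.148. Without SLU7 replicate 2 the list passed (adjusted p = 0.0447), and without SLU7 replicate 3 its median was 0.03. Without the dimmer clusters it also passed (median -0.73, adjusted p = 0.0232).

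Lipid genes were lower in each of 3 lists with the preset correlation, and none of the 3 passed with an estimated one (adjusted p from 0.12 to 0.155 with an estimated correlation). Fry called all 3 lower (adjusted p = 0.0328 for cholesterol synthesis, 0.00982 for fatty acid synthesis and 0.0231 for fatty acid oxidation). Of 19 measured genes of cholesterol synthesis and uptake, 17 were below 0, with a median of -0.84 or 1.79-fold lower (-0.61 within the pair and -0.85 within the other 4). INSIG1, the sterol-regulated brake on this pathway, fell 4.08-fold, and 18 members did not pass. Adjusted over the list alone, 7 fell and 1 rose (IDI1, by 0.87 log2 units). The camera adjusted p was 3.25e-05, and adjusted p = 0.155 with an estimated correlation. The 20 lipogenic genes had a median of -0.30 (-0.30 within the pair and -0.33 within the other 4), none passed over all genes, and 5 fell over the list alone: ACLY (-1.60), FADS2 (-1.28), SCD (-1.25), ACSS2 (-1.13) and AGPAT2 (-1.09). Their camera adjusted p was 0.0075, and adjusted p = 0.12 with an estimated correlation. The median was -0.19 without control replicate 2 and -0.16 without SLU7 replicate 3. Among 26 genes of fatty acid oxidation and ketogenesis the median was -0.35 (-0.44 within the pair and -0.28 within the other 4, and -0.53 without control replicate 2). ETFB, the beta subunit of the electron transfer flavoprotein, fell 3.28-fold, and 25 did not pass. Adjusted over the list alone 4 fell, the others being HSD17B4 (-2.20), ACADVL (-1.56) and ECI2 (-0.87), and the camera adjusted p was 0.00143 (adjusted p = 0.12 with an estimated correlation).

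Epithelial junction and keratin genes had a median of -0.26 over 21 members (-0.25 within the pair and -0.46 within the other 4). CDH1, which encodes E-cadherin, fell 3.63-fold (from 10.15 ± 0.30 to 8.29 ± 0.38 log2 units, SD, n = 3), and 20 members did not pass. Adjusted over the list alone 5 fell, the others being CTNND1 (-1.78), GJB1 (-1.42), CGN (-1.30) and CLDN1 (-0.80), and 1 rose (MARVELD3, by 0.87). The list had a camera adjusted p of 0.00408, and adjusted p = 0.12 with an estimated correlation, while fry called it lower (adjusted p = 0.00738). The mesenchymal list was not called, with a median of -0.18 over 31 genes and a camera adjusted p of 0.075 (0.0338 without SLU7 replicate 1). None of it passed over all genes, and over the list alone 2 fell, FN1 (-1.49) and VIM, vimentin (-3.30, from 6.63 ± 1.21 to a dim 3.33 ± 0.76, SD, n = 3). Oncofetal liver markers were called lower, with a median of -0.34 over 15 genes (-0.66 within the pair and -0.43 within the other 4) and a camera adjusted p of 0.00481 (adjusted p = 0.32 with an estimated correlation). Without SLU7 replicate 1 that adjusted p was 0.0717, and fry did not call the list (adjusted p = 0.114). No oncofetal member passed over all genes, and 4 fell over the list alone: CD24 (-1.54), PROM1 (-1.10, to a dim 4.75), SOX9 (-0.95) and MDK (-0.85). The same list was 0.54 log2 units lower, by its median, in the 2 arrays that stand apart than in the other 4.

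The only list called higher, with the preset correlation, held second-step splicing factors and SLU7 partners, without SLU7 (second-step splicing for short). It was drawn up with other spliceosome proteins too, among them CDC5L, PRPF19 and DHX15, so its rise cannot be assigned to the second step. Its 20 members had a median of 0.54 log2 units, or 1.45-fold higher, and 17 were above 0. The camera adjusted p was 3.81e-04, and adjusted p = 0.197 with an estimated correlation. The self-contained test fry did not call it either (adjusted p = 0.0675). No single member passed over all genes or over the list alone. In the 2 arrays that stand apart the list's median was 0.35 lower than in the other 4. It was higher with SLU7 siRNA both within that pair (0.84) and within the other 4 arrays (0.45). The 41 proteins of the small nuclear ribonucleoproteins had a median of 0.08 (camera adjusted p = 0.331) and the 35 SR proteins and hnRNPs one of 0.13 (adjusted p = 0.242). In each, no member passed over all genes and 1 rose over its list alone, PRPF4 (1.63) and HNRNPA1 (2.35). HNRNPA1 has many near-identical pseudogenes, so its value is uncertain. Without any 1 array the median of the small nuclear ribonucleoprotein list ran from -0.068 (without SLU7 replicate 3) to 0.18 (without control replicate 1), and that of the SR and hnRNP list from 0.033 (without SLU7 replicate 3) to 0.11.

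**Figure D3:**
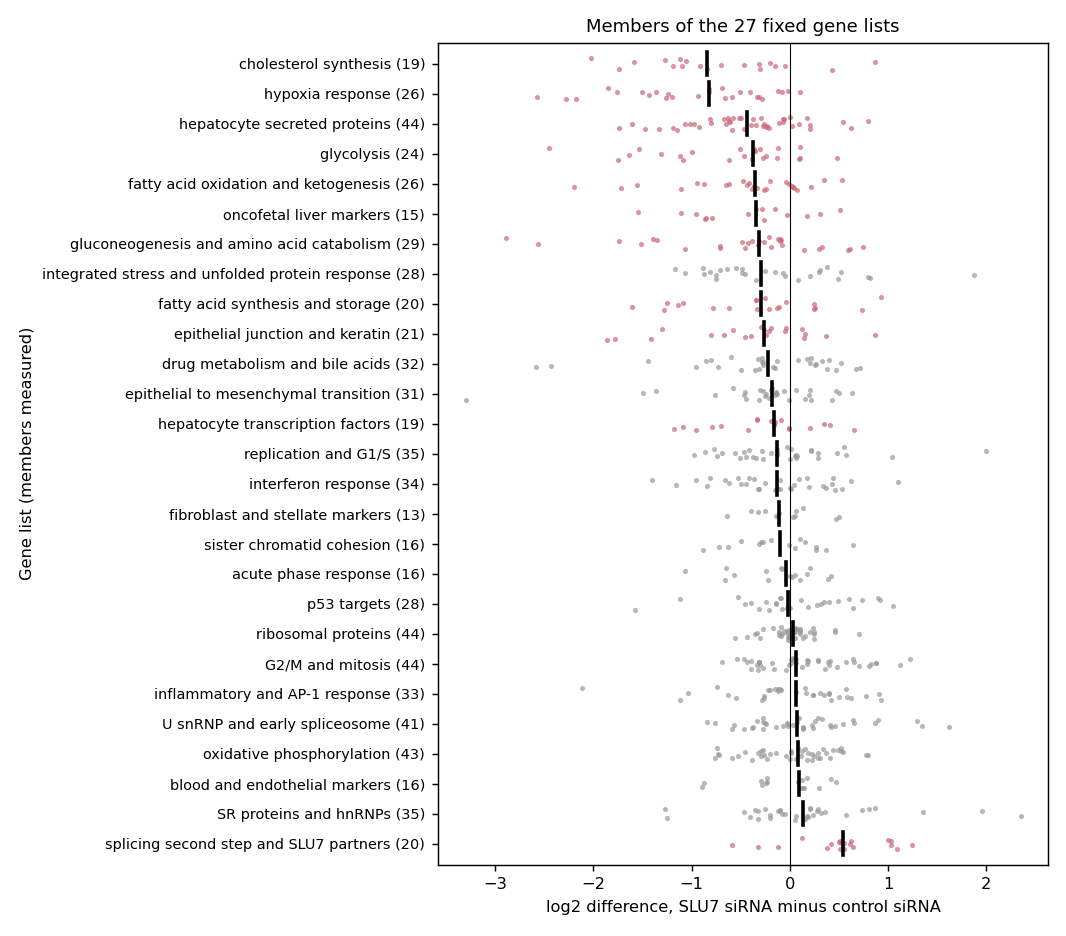
Log2 difference between SLU7 siRNA and control siRNA for each measured member of the 27 gene lists (points; number of members in brackets), with the list median as a black bar; red lists passed camera at an adjusted p under 0.05 with the preset correlation and grey ones did not. The medians run from -0.84 for cholesterol synthesis to 0.54 for the list of second-step splicing factors and SLU7 partners.

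The remaining lists were not called. Replication genes had a median of -0.13 over 35 members and mitosis genes one of 0.07 over 44 (camera adjusted p = 0.331 for both). No member of either passed over all genes. Over the lists alone none of the replication genes passed and 1 mitosis gene rose, CDCA8 (1.23). In the 2 arrays that stand apart the mitosis list was 0.63 log2 units lower than in the other 4, and without SLU7 replicate 1 it passed as higher (median 0.16, adjusted p = 0.0141). Sister chromatid cohesion genes had a median of -0.10 (adjusted p = 0.365) with none passing either way, and were 0.40 log2 units lower in the pair of arrays. Among 28 p53 targets the median was -0.02 and the mean 0.06, and the test pointed upward (adjusted p = 0.821). CYFIP2, a p53-induced actin regulator, fell 2.98-fold, and over the list alone 2 fell, the other being TNFRSF10B (-1.12). In the stress and unfolded protein response, SLC7A11, the cystine transporter and a target of ATF4, rose 3.68-fold against a list median of -0.30 (camera adjusted p = 0.0656), with 2 members higher over the list alone (DDIT3 being the other, 0.81) and 3 lower (CEBPG -1.16, HYOU1 -1.07, PHGDH -0.89). That list was 0.30 log2 units lower in the pair of arrays, and passed without control replicate 2 (adjusted p = 0.00425) or without SLU7 replicate 2 (adjusted p = 0.0239). Interferon-induced genes had a median of -0.13 over 34 genes (adjusted p = 0.162) and were 0.15 log2 units lower in the pair. Their median ran from -0.27 (without control replicate 2) to -0.027 (without SLU7 replicate 1). Inflammatory and AP-1 genes had a median of 0.07 and a mean of -0.01, with the test pointing upward (adjusted p = 0.855). Acute phase genes had a median of -0.04 (adjusted p = 0.628), ribosomal proteins 0.03 (adjusted p = 0.808) and oxidative phosphorylation genes 0.08 (adjusted p = 0.951), the last being 0.36 log2 units lower in the pair and running from -0.20 (without control replicate 2) to 0.20 (without SLU7 replicate 1). No member of these 5 lists passed over all genes or over its list alone. Markers of cell types foreign to a hepatoma culture showed no call: blood and endothelial markers had a median of 0.10 and a mean of -0.07, with the test pointing downward (adjusted p = 0.82), and fibroblast and stellate markers a median of -0.11 (adjusted p = 0.808).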

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

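The block for the array split and the analysis of 4 arrays were chosen after the data were seen. No direction was reversed. The 11 called lists kept their direction under every alternative. So did the 28 called genes named in the text, wherever a setting gave them a value (the filter on dim clusters left 23 of the 28). For these genes that decides nothing. Their groups do not overlap, so leaving out arrays cannot reverse them, and the blocks leave the log2 differences unchanged. Which single genes passed depended on the setting, from 25 higher and 56 lower. The filter on dim clusters gave 196 and 278 over 9354 clusters tested (64 shared with the 81), the intensity trend with robust shrinkage 173 and 268, array weights 221 and 354, and the array split as a block 357 and 426. Quantile normalization gave 29 and 71 and median centring 25 and 56. Apart from the dim filter, each of these settings called all 81. The limma counts were 0 and 0 at a threshold of 0.01 (lowest adjusted p 0.0316, 2450 clusters at an unadjusted p under 0.05), in the 4 arrays (2922 at an unadjusted p under 0.05), and 0 to 0 in each direction without any 1 array, where fewer arrays widen the error. The scaling alternatives moved the median of all clusters by at most 0.00698.

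With replicate number as a block the counts were 0 and 0 (1845 at an unadjusted p under 0.05), and SLU7 stayed at -1.51 (adjusted p = 0.219). The same-numbered arrays deviated from their group means with correlations of -0.381, -0.314 and 0.141, which shows no likeness by number. The 2 arrays that stand apart carry different numbers, which can itself lower such correlations. Whether the numbers pair the samples therefore stays unknown, and so does what the loss of calls says of the effect. No array correlated best with its own number (highest 0.517, control replicate 2 with SLU7 replicate 1).

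SLU7 passed with the dim filter (-1.51, adjusted p = 0.0213), the trend with robust shrinkage (-1.51, adjusted p = 0.033), array weights (-1.61, adjusted p = 0.0269) and the array split as a block (-1.51, adjusted p = 0.043). Without any 1 array it ran from -1.69 to -1.25 (adjusted p from 0.0889 to 0.272).

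With an estimated correlation camera called no list. This loss does not by itself show that correlated genes carry the lists. Glycolysis lost its call with an estimated correlation of -0.035, below the preset 0.01. The medians do not change with the test: hepatocyte transcription factors -0.16, secreted proteins -0.43, oncofetal markers -0.34, gluconeogenesis -0.31, glycolysis -0.37, hypoxia -0.83, cholesterol -0.84, fatty acid synthesis -0.30, fatty acid oxidation -0.35, epithelial junction -0.26 and second-step splicing 0.54, with adjusted p from 0.109 to 0.32. Fry called 9 of the 11 lists, while oncofetal markers (-0.34, adjusted p = 0.114) and second-step splicing (0.54, adjusted p = 0.0675) missed its threshold. Hepatocyte transcription factors missed it with the replicate block (-0.16, adjusted p = 0.0507), dim filter (-0.15, 0.207), quantile normalization (-0.17, 0.0521), array weights (-0.22, 0.0607), the array split as a block (-0.16, 0.0606) and 4 arrays (-0.20, 0.1). New calls were drug metabolism with the dim filter (-0.73, adjusted p = 0.0232), the mesenchymal list with the trend (-0.18, adjusted p = 0.0478), and the stress response with the dim filter (-0.47, adjusted p = 0.0097), trend (-0.30, 0.0133), array weights (-0.24, 0.0468) and 4 arrays (-0.27, 0.0474). The cause of these changes was not tested.

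Leaving out 1 array gave median ranges of -0.32 to -0.10 for hepatocyte transcription factors (called in 3 of 6), -0.49 to -0.26 for oncofetal markers (5 of 6), -0.26 to 0.026 for drug metabolism, -0.29 to -0.071 for the mesenchymal list, -0.054 to 0.16 for mitosis (1 of 6 each) and -0.41 to -0.19 for the stress response (2 of 6). The other 9 called lists passed in all 6, of which fatty acid synthesis ran from -0.43 to -0.16 (-0.16 without SLU7 replicate 3, -0.19 without control replicate 2) and fatty acid oxidation from -0.53 (without control replicate 2) to -0.26. Medians of 8 further uncalled lists also moved without 1 array: replication -0.19 to -0.047, cohesion -0.19 to 0.053, p53 targets -0.047 to 0.047, inflammation -0.065 to 0.20, acute phase -0.12 to 0.0098, ribosomal proteins -0.021 to 0.083, blood and endothelial markers -0.18 to 0.11, and fibroblast and stellate markers -0.18 to 0.035. No detection calls were used, so how far signal over background limits dim clusters is unknown.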

Other observations

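The gene families below were defined after a first look at the results, and the tests of exchanged array labels, of the interferon response, and of brightness and array split for the zinc finger genes were chosen only after the results were seen.

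Zinc finger genes lay higher with SLU7 siRNA by camera's preset correlation, but not with an estimated one (adjusted p = 0.138 with an estimated correlation). Of 408 measured genes with ZNF symbols, most of which encode C2H2 zinc finger transcription factors, 307 had a positive difference, with a median of 0.29 log2 units. Over all genes 2 passed, ZNF75A and ZNF304. Camera called 5 of 28 families grouped by symbol, and the ZNF family had an adjusted p of 2.71e-09 with the preset correlation. The homeobox HOX genes had a median of 0.25 over 36 genes, 27 of them above 0 (adjusted p = 0.0256, and adjusted p = 0.27 with an estimated correlation). Mitochondrial ribosomal proteins had a median of 0.19 over 78 genes (adjusted p = 0.0256, and adjusted p = 0.766 with an estimated correlation). Aldo-keto reductases and aldehyde dehydrogenases, detoxifying enzymes abundant in liver, had a median of -0.34, with 18 of 24 below 0 (adjusted p = 0.0199, and adjusted p = 0.27 with an estimated correlation). Fry called the zinc finger genes (adjusted p = 0.0445) and the aldo-keto reductases and aldehyde dehydrogenases (adjusted p = 0.0059). It did not call the HOX genes (adjusted p = 0.147) or the mitochondrial ribosomal proteins (adjusted p = 0.538). Each of these 4 families kept its direction under quantile normalization, median centring and each analysis without 1 array. The size held less well for the mitochondrial ribosomal proteins, whose median was 0.04 without control replicate 2 and reached 0.29 without SLU7 replicate 1.

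Replication-dependent histone genes, which have no introns, were tested for the hypothesis that transcripts not needing splicing lie higher when a splicing factor is reduced. Their median was -0.33, with 21 of 27 below 0 (camera adjusted p = 0.0256, and adjusted p = 0.696 with an estimated correlation). Fry did not call the family (adjusted p = 0.345), and the median was -0.52 without control replicate 2. The histone genes thus did not lie higher. This family alone was set against the hypothesis, so it does not decide it for other genes without introns.

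The higher level of the zinc finger genes was set against 3 technical explanations. The brightness of these genes is not enough, since the family median lay at percentile 100 of 10000 random lists matched on mean expression. The array split holds 1 array of each group in its smaller part, so it is balanced and adds nothing by itself to the group difference; the median was 0.32 within the other 4 arrays and 0.24 between the single arrays of the pair, so the pair alone does not carry it. The median without the uppermost quartile of the family, 0.14, decides nothing about a few genes with large changes, since with 307 of 408 above 0 it could not fall below 0. An effect of SLU7 reduction on these genes is a candidate explanation, as a hypothesis found and tested on the same arrays. Correlated genes stay open too. The loss of the camera call with an estimated correlation (adjusted p = 0.138) does not decide this, since the glycolysis list lost its call with a negative estimate (-0.035).

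The lower metabolic and hypoxia lists may reflect SLU7 reduction or a technical cause. All 10 lists called lower had negative medians within the 4 arrays and between the single arrays of the pair, which argues only against the pair alone carrying them, since the split is balanced over the groups; 9 of the 10 lay under the 2.5 percentile of brightness-matched random lists, the exception being hepatocyte transcription factors at 9.72. An interferon response to double-stranded RNA that was stronger with the SLU7 siRNAs would raise the interferon list, whose median was -0.13 (-0.27 to -0.027 without any 1 array). Both groups received siRNA, so a response common to both would cancel in this comparison and was not tested. Effects of these siRNAs on targets other than SLU7 stay open.

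For the hypoxia and glycolysis lists, neither less HIF1A nor less EPAS1 transcript was settled: HIF1A differed by -0.081 (95% interval -0.73 to 0.57) and EPAS1 by -1.24 (-2.0 to -0.48, adjusted p = 0.148). EPAS1 is itself a member of the hypoxia list and passed when adjusted over that list alone (adjusted p = 0.015). The lower level of the list eases that adjustment, so it lends EPAS1 no support as the cause. EPAS1 was also called lower with the array split as a block, which was chosen from these same data. Less EPAS1 transcript stays open only because the test over all clusters could not decide.

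Control replicate 2 and SLU7 replicate 1 stood apart from the other 4 arrays on the first component. Exchanged labels would put SLU7 lower in the control array, but it was 1.17 log2 units higher there. Fewer dividing cells would lower replication genes as well as mitosis genes, yet the replication list lay at percentile 27.8 of matched random lists in the pair minus the other 4, while the mitosis list lay at percentile 0. That argues only against a fall of both lists together. A cell cycle difference that touches mitosis genes alone stays open. A compressed signal range is a possible explanation for a part: the difference of the pair from the others correlated with mean expression across clusters at -0.113, the most negative of 15 pairs of arrays (next -0.0723), but that covers 1.27% of its variance. What else sets the pair apart, such as a shared processing day, is not given in the sources used here.

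Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many calls: 81, against 0 as the highest of the others. The splits are too few for a share under 0.05.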
